A study of Solanum lycopersicum with 8 samples.

How the data were processed

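Chromatin accessibility was measured by ATAC-seq, in which a transposase inserts sequencing adapters into open chromatin, in 6 replicates of the terminal leaflet of young leaves of tomato cultivar M82. Chromosome contacts were measured by Hi-C, in which cross-linked DNA ends that lie close in the nucleus are ligated and sequenced, in 2 replicates of inflorescences of the anantha mutant in the same background. These mutant inflorescences are cauliflower-like masses enriched in meristems, and per the labels' protocols they were harvested 10 weeks after sowing, from different plants. Per the labels' protocols, each leaf sample weighed 1 g and each transposase reaction held 100000 nuclei. The growth text of the labels names the anantha mutant for the ATAC-seq plants as well, whereas the genotype label of the leaf samples reads M82; the genotype label was followed here.

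The values came as 2 lists for the whole series, with 1 list per assay, so the spread between replicates could not be computed and every value below is a value of the authors' combined list. The leaf list holds peaks with a start, an end, a score and a −log10 q. Its score is the authors' per-peak score, deposited as a whole number with a ceiling of 1000, and it was used only to rank or filter peaks within the list. The coordinates and the −log10 q are deposited as the authors' caller gave them. Per the submitters' processing notes, the tools were Trimmomatic, BWA, Picard, SAMtools, bedtools, Genrich 0.6 and HiC-Pro 3.1.0; their settings are not given in the sources used here. The names of the deposited lists give Genrich for the peaks and FitHiC, a caller of contacts above a distance expectation, for the loops. A test on the list showed that the score times the width divided by 1000 was at least 200 after rounding for each of the 39170 peaks below the ceiling, as a lower limit on that area would give. No 2 neighbouring peaks on a chromosome lay closer than 31 bp. In all, 2115 peaks (3.03%) had a q above 0.05, and the highest q listed was 0.135. The loop list holds the midpoints of both anchor bins of each loop, in 5 kb bins, with no contact count, score or q, so neither the depth nor the strength of a loop is known. The read depth behind a peak is also unknown.

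The sequence names of the leaf list are those of the SL4.0 assembly. The loop list names no assembly. Its last anchors lay past the last SL4.0 peak on 12 of 12 chromosomes, by 0.245 to 5.17 Mb, so it was treated as a different assembly. The gene table used here belongs to a further assembly, SLM_r2.1, and the anchors passed its last gene on 3 chromosomes. Coordinates were therefore never overlaid between the lists or with genes, and no gene is named. The planned tests of peaks against genes, of anchors against peaks, and of the gene lists, which had been fixed before the data were examined, were not run for this reason. They included lists of meristem, floral and leaf shape genes and of families named by product. The peak and loop counts and their alternatives were also fixed beforehand, and all other comparisons were chosen after the files had been seen. The rule for named items ranks peaks by score; because of the ties at 1000, peaks were ranked further by −log10 q. The part of that rule that ranks loops by q could not be used. Other positions given in the text, such as the widest peaks, the longest loops and the busiest anchors, were chosen after their values were seen.

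A peak is called an accessible chromatin region (ACR). Peak starts were read as BED starts and printed 1-based. The extent of a chromosome is the position of the last ACR or the last anchor bin in that list. It was not corrected for assembly gaps or for repeats where reads cannot be placed. Chromosome ends are the first and last 20% of the extent (40% together), and the interior is the middle 60%; a feature belongs to the part that holds its midpoint. For each of the 12 chromosomes the log2 ratio of densities, or the difference of medians, was computed, and its mean over chromosomes was tested with an exact two-sided sign-flip permutation test over all 4096 sign patterns, whose smallest possible p is 0.000488. The chromosomes are parts of 1 list and not biological replicates, so these p-values measure how uniform a pattern is over chromosomes. On 100 simulated sets of the 69143 chromosomal ACRs with a density ratio of 4, the mean ratio recovered was 4.00, and the exact permutation test called 100 sets at the 0.05 threshold. With no difference put in, it called 8 of 100 sets. The simulated ratio was the same on every chromosome and the ACRs were placed independently of each other. The listed ACRs differ in both respects, so these sets check the calculation and not the test on data like these.

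Gaps between neighbouring ACRs were compared with 10000 random placements of the ACRs within their own 1 Mb window. Anchor sharing was compared with 100000 sets in which every loop was moved as a rigid pair by 50 to 500 kb. Correlations over chromosomes were tested with 100000 permutations, two-sided, with Benjamini-Hochberg adjustment over 4 relations. Intervals on shares are exact Clopper-Pearson 95% intervals and cover counting error only. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. Alternatives were only ACRs at or above the median score (894), merging of ACRs within 150 bp, a minimum width of 150 bp or 500 bp, other definitions of the chromosome ends, leaving out chromosome 2, leaving out the shortest loops, and other random placements.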

Results

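The leaf ATAC-seq list, from 6 replicates, held 69690 ACRs, of which 69143 lay on chromosomes 1 to 12 and 547 on unplaced sequence. The inflorescence Hi-C list, from 2 replicates, held 9573 loops, each joining 2 bins of 5 kb on the same chromosome. Neither list carried values per replicate, so errors below are spreads over chromosomes or counting intervals. The series concerns cis-regulatory sequence in plants, and the lists bear on where such sequence may lie in tomato, through open chromatin and through contacts between distant sites.

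Accessible chromatin occupied a small part of the leaf genome. The chromosomal ACRs covered 62.3 Mb, or 8.06% of the summed extents of 773 Mb. Their median width over the whole list was 665 bp, with quartiles of 456 and 1023 bp. The chromosomes carried 90.8 ± 23.2 ACRs per Mb (SD, n = 12 chromosomes). Chromosome 2 was the densest, at 141 ACRs per Mb, followed by chromosome 6 at 124 and chromosome 3 at 110 ACRs per Mb. Chromosome 12 was the sparsest, at 67.5 ACRs per Mb. Median widths differed little between chromosomes, from 646 bp on chromosome 11 to 688 bp on chromosome 2.

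ACRs were concentrated at the chromosome ends. The chromosome ends held 53732 ACRs, or 77.7% of those on chromosomes (95% interval 77.4 to 78.0%), in 40% of the extent. Density was 174 ACRs per Mb of extent at the ends and 33.2 ACRs per Mb in the interior, with any gaps and repeats included in the extent. Each extent was also cut into 10 equal parts, numbered from its start. Over all chromosomes, part 2, counted with the ends, held 3187 ACRs, fewer than the 6349 of part 8 in the interior. The mean ratio over chromosomes was 5.97-fold (95% interval 4.26 to 8.35), and the ends were denser on 12 of 12 chromosomes (exact sign-flip permutation p = 0.000488, the smallest possible). In tomato the chromosome interiors are largely pericentromeric heterochromatin, and genes are densest in the distal arms. The ratio was highest on chromosome 7, at 9.71-fold, and on chromosome 4, at 9.54-fold. It was lowest on chromosome 2, at 1.55-fold. There the first 20% held 145 ACRs, the last 20% held 3695 and the interior 3719. Chromosome 2 of tomato has a short arm that carries the ribosomal DNA array. On chromosomes 5 and 11 the first 20% held more ACRs than the last, with 2309 against 1713 on chromosome 5 and 1887 against 1582 on chromosome 11. The 1 Mb window with the most ACRs was at 62 to 63 Mb of chromosome 3, with 415, and the median window held 29.

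**Figure D1:**
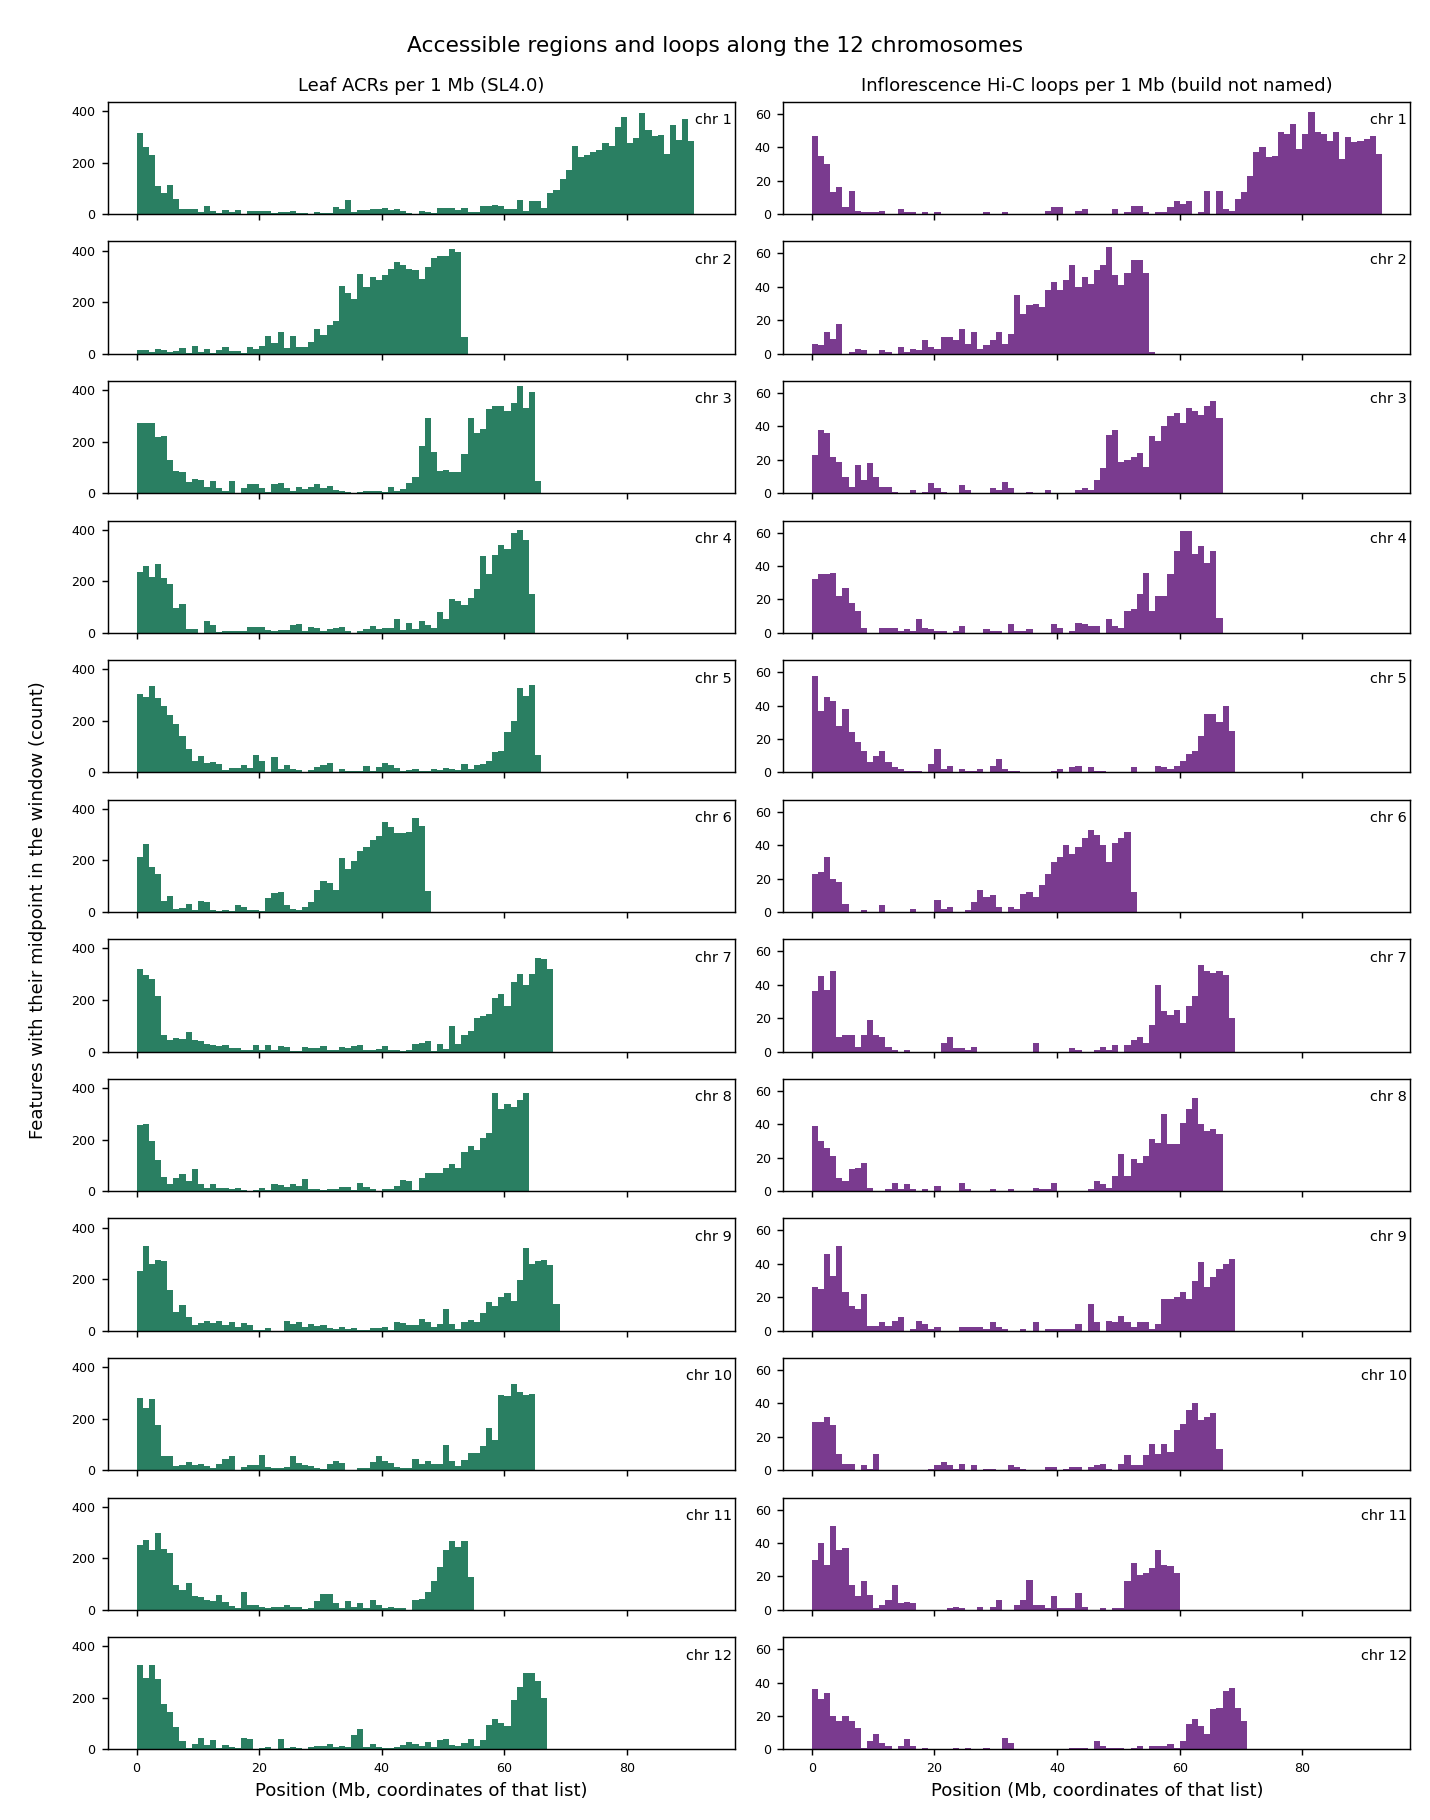
ACRs in leaf (left, SL4.0 coordinates) and Hi-C loops in inflorescence (right, coordinates of an assembly that the list does not name) per 1 Mb window along chromosomes 1 to 12, as counts of features with their midpoint in the window; the x axis is position in Mb. Both lists pile up towards the chromosome ends, and chromosome 2 has a single dense side, with 145 ACRs in its first 20% and 3695 in its last 20%.

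Long stretches held no ACR. The longest ran from position 21972720 to 24112175 on chromosome 9 (SL4.0), 2.14 Mb, followed by 1.63 Mb from 9677145 to 11311068 on chromosome 4, which lies in the first 20% of that chromosome. Of 766 full 1 Mb windows, 5 held no ACR. How much of such stretches is assembly gap or repeat was not examined. ACRs of the interior also had a weaker −log10 q. The median was 2.60 at the ends and 2.46 in the interior, and the mean difference over chromosomes was 0.19 (95% interval 0.09 to 0.29; exact sign-flip permutation p = 0.00293). The ends had the higher median on 10 of 12 chromosomes, the exceptions being chromosomes 2 and 6. The difference was 0.09 with ends of 10% on each side and 0.30 among ACRs of at least 500 bp. Interior ACRs were narrower by a mean of 29.4 bp (95% interval 12.9 to 45.9 bp; exact sign-flip permutation p = 0.00488), with chromosomes 9 and 12 as the exceptions. With ACRs within 150 bp merged, the width difference was 80.5 bp.

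ACRs occurred in close groups. A following neighbour lay less than 1 kb away for 52.3% of chromosomal ACRs, and the median gap was 887 bp. Random placement of the same ACRs within their own 1 Mb windows gave 34.1% (95% range 33.8 to 34.4%; permutation p = 0.0002, the smallest that 10000 placements can give). Placement within 100 kb windows gave 37.0%. Placed ACRs could overlap each other and could fall where no ACR can be called. The excess may therefore reflect in part where ACRs can be called. Gaps shorter than 100 bp made up 18.6% of all gaps. With ACRs within 150 bp merged, the share was 37.9% against 30.1% for random placement, and among ACRs at or above the median score it was 32.6% against 21.2%.

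The ACRs with the strongest −log10 q among those at the score ceiling were partly on unplaced sequence, which held 4 of the first 10. The strongest on a chromosome spanned 9562835 to 9566387 on chromosome 11, with a −log10 q of 17.4. Chromosome 3 held 3 of the first 10, at 56173410 to 56175947 with a −log10 q of 17.0, at 61200035 to 61205888 with 16.8, and at 64707632 to 64719430 with 16.7. The others lay at 42100878 to 42102022 on chromosome 4, with a −log10 q of 16.5, and at 63673008 to 63676299 on chromosome 9, with 16.4 (SL4.0 throughout). The files pair none of these positions with genes.

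Most chromatin loops in the meristem-enriched inflorescences were short. The median span was 20 kb, and the quartiles were 10 and 60 kb. The shortest span listed, 10 kb, accounted for 3916 loops, or 40.9% (95% interval 39.9 to 41.9%). The next spans were far rarer, with 492 loops of 15 kb, 470 of 20 kb and 495 of 25 kb. Loops longer than 100 kb numbered 1645 (17.2%), and 319 were longer than 500 kb. The longest spans listed were 1000 kb, on chromosomes 5, 9 and 11. Whether the caller had an upper distance limit is not given. Spans and their medians therefore hold for the listed range of 10 to 1000 kb. No loop had another loop within 1 bin at both ends, whereas 2465 had one within 2 bins. Adjacent calls were therefore probably removed or merged before listing, so loop counts and spans describe a thinned list.

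Loops were also concentrated at the chromosome ends. The ends held 7684 loops, or 80.3% (95% interval 79.5 to 81.1%). Density was 24.0 loops per Mb of extent at the ends and 3.93 in the interior, again with any gaps and repeats included. Of the 10 equal parts of the extents, part 2, counted with the ends, held 435 loops, fewer than the 924 of part 8 in the interior. The mean ratio over chromosomes was 7.70-fold (95% interval 5.11 to 11.6), with the ends denser on 12 of 12 chromosomes (exact sign-flip permutation p = 0.000488, the smallest possible). Without the 10 kb loops it was 5.13-fold. Chromosome 7, at 16.8-fold, and chromosome 12, at 15.3-fold, had the steepest contrast, and chromosome 2, at 1.67-fold, the flattest. Of 796 full 1 Mb windows, 200 held no loop. The longest stretch without an anchor was 9.33 Mb, on chromosome 12.

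Loops of the interior had a longer median span than those of the ends, but neither part was uniform. The pooled median span was 15 kb at the ends and 70 kb in the interior. Among the 10 equal parts of the extents, the pooled medians at the ends were 20 kb in part 1, 130 kb in part 2, 25 kb in part 9 and 10 kb in part 10. In the interior they were 160 to 275 kb in parts 3 to 6, 67.5 kb in part 7 and 35 kb in part 8. Part 2 thus had a longer median than parts 7 and 8 of the interior. The interior median exceeded that of the ends on 12 of 12 chromosomes, by a mean of 7.83-fold (95% interval 4.93 to 12.4; exact sign-flip permutation p = 0.000488, the smallest possible). The ratio was 4.30-fold without the 10 kb loops and 4.73-fold with ends of 10% on each side. The medians on chromosome 9 were 25 kb at the ends and 290 kb in the interior, and those on chromosome 2 were 15 and 25 kb. Loops longer than 200 kb made up 28.2% of interior loops and 5.41% of those at the ends. Loops of 10 kb made up 24.5% of interior loops (95% interval 22.5 to 26.5%) and 45.0% of those at the ends (43.8 to 46.1%).

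**Figure D2:**
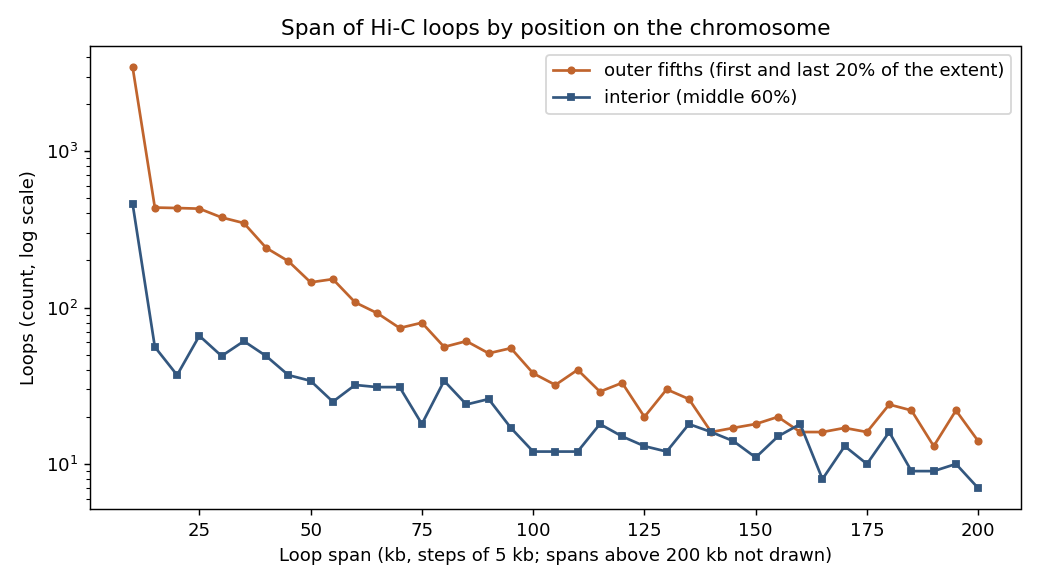
Number of inflorescence Hi-C loops (y axis, log scale) at each span from 10 to 200 kb (x axis, steps of 5 kb), for loops with their midpoint in the chromosome ends (circles) and in the interior (squares). Both parts peak at 10 kb, and the count falls more slowly with span in the interior.

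Some bins anchored several loops. The 9573 loops used 15570 distinct anchor bins, 9.71% of the bins within the extents. Of these, 2983 bins (19.2%) anchored at least 2 loops. Local shifts of the loops gave 14.7% (95% range 14.2 to 15.2%; permutation p = 2e-05, the smallest possible). Placement anywhere on the chromosome gave 6.28%. Without the 10 kb loops the share was 14.7%, against 7.69% for shifts. The shifted loops were allowed to lie within 1 bin of each other at both ends, which the listed loops never did. They could also land in any bin, whether or not loops could be called there, so the excess need not mean preferred anchors. The busiest bin, from 57355001 to 57360000 on chromosome 7, anchored 7 loops, and the bin from 76375001 to 76380000 on chromosome 1 anchored 6. A further 11 bins anchored 5 loops each, of which 3 lay on chromosome 1, at 76420001 to 76425000, at 76455001 to 76460000 and at 78715001 to 78720000. These positions are in the unnamed assembly of the loop list.

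The 2 lists come from different tissues and genotypes and were not overlaid by coordinate; they were compared by totals per chromosome and by the share of each list in the ends of its own extents. Chromosomes with more leaf ACRs had more inflorescence loops. The counts correlated with Pearson r = 0.97 and Spearman rho = 0.98 over the 12 chromosomes (permutation p = 2e-05 for each, the smallest possible; adjusted 4e-05). Without chromosomes 1 and 2, the farthest from the median, r was 0.92. Densities per Mb correlated with r = 0.96 and rho = 0.99 (permutation p = 2e-05 for each; adjusted 4e-05), and r was 0.94 without chromosomes 2 and 6. The correlations with extent did not pass the threshold. ACR count and extent gave r = 0.39 and rho = 0.06 (permutation p = 0.2 and 0.9; adjusted 0.3 and 0.9), and r = 0.01 without chromosomes 1 and 2. Loop count and extent gave r = 0.29 and rho = −0.13 (permutation p = 0.4 and 0.7; adjusted 0.4 and 0.9), and r = −0.13 without chromosomes 1 and 2.

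**Figure D3:**
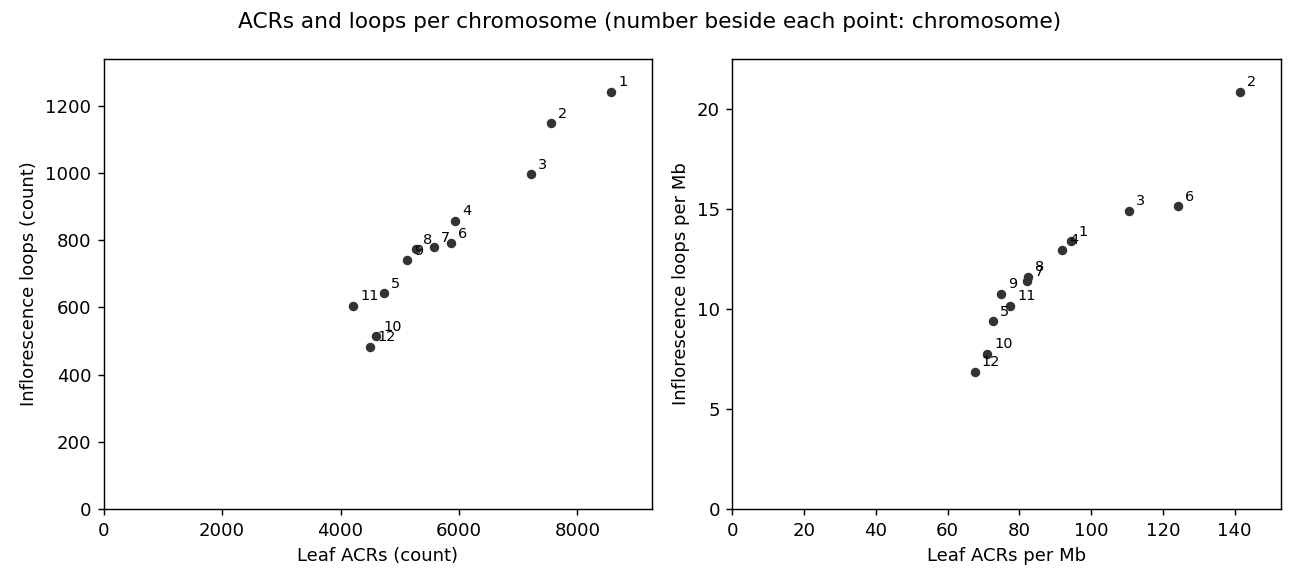
Inflorescence loops against leaf ACRs for chromosomes 1 to 12, as counts (left) and per Mb of each list's own extent (right); each point is a chromosome, with its number beside it. Chromosome 11 has the fewest ACRs, with 4210 ACRs and 605 loops, chromosome 12 the fewest loops, with 4500 ACRs and 483 loops, and chromosome 1 the most of both, with 8572 ACRs and 1241 loops.

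Measured in each list's own extents, the contrast between ends and interior was steeper for loops than for ACRs by 0.37 on the log2 scale (95% interval 0.14 to 0.59; exact sign-flip permutation p = 0.00195; steeper on 10 of 12 chromosomes). This order rested on the 10 kb loops: without them the difference was −0.22 (exact sign-flip permutation p = 0.0469). With ends of 10% on each side it was 0.05 (exact sign-flip permutation p = 0.263).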

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

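The tests of unplaced sequence and of wide ACRs were chosen after the list had been seen. The exception was the test of neighbouring ACRs, whose criteria had been set before it was run. Unplaced SL4.0 sequence, which the comparisons of chromosomes leave out, held 547 ACRs and is described here because no comparison used it. They were sparser than on chromosomes, at 56.9 against 89.5 ACRs per Mb, yet covered 8.78% of the extent against 8.06%. More of them stood at the score ceiling (55.4% against 43.7%), and the highest −log10 q was 42.3 against 17.4 on the chromosomes.

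Wide ACRs accompanied this signal. Of the 55 ACRs wider than 10 kb, 12 lay on unplaced sequence, which made up 2.19% of its ACRs against 0.0622% on chromosomes (odds ratio 36.0, given without an interval because neighbouring wide ACRs are not independent). The widest spanned 3362266 to 3408055 of the unplaced sequence, 45.8 kb, and 3 of the 10 widest lay in a row on chromosome 8 between 9484880 and 9560996. Sequence with more copies in the plant than in the assembly, such as organellar or repeated DNA, was not tested as an explanation: the odds ratio restates what was seen in the list and gives it no support, and copy number was not measured. Joining of ordinary ACRs in dense stretches was left open: wide ACRs had a median of 24 other ACRs within 50 kb against 27 for all, a difference of −3 with a bootstrap interval of −8 to 2. Neighbouring wide ACRs are not independent here either. Joining would itself use up the neighbours counted, so this count cannot decide. No biological explanation was tested.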

How the results depend on the processing

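All alternatives except those for the ACR and loop counts were chosen after seeing the data. The ACR count was 34849 at or above the median score, by construction. It was 53493 with ACRs within 150 bp merged and 69642 with a minimum width of 150 bp. Merging loops within 1 bin at both ends left 9573, since none were that close. The difference between loops and ACRs in their concentration at the ends fell to 0.0543 with ends of 10% on each side and turned to −0.219 without the 10 kb loops, so its direction depends on those loops; the cause was not tested further. Under the alternatives run, the ratio of densities stayed between 5.33-fold and 6.75-fold for ACRs and between 5.13-fold and 8.84-fold for loops. The ratio of median spans stayed between 4.30-fold and 9.02-fold. The difference in −log10 q, 0.186 as reported, ranged from 0.0919 with ends of 10% to 0.300 among ACRs of at least 500 bp. The difference in width, 29.4 bp as reported, ranged from 24 bp with ends of 25% to 80.5 bp with close ACRs merged. The share of close neighbours fell to 32.6% at or above the median score, and the share of shared anchors to 14.7% without 10 kb loops, where shifts gave 7.69%. These results, the share of 10 kb loops and the correlation over chromosomes kept their direction and, where tested, their side of the threshold. No paired analysis was possible because neither list carries replicate values, and leaving out a replicate was not possible for the same reason. The settings listed beforehand for peaks against genes, anchors against peaks and gene lists were not run, because the assemblies differ, and a stricter set of loops was not run, because the list has no loop strength. Depth is unknown for both lists, so an absent ACR or loop says nothing about the limit of detection.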

Other observations

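The tests of interior spans, of removal beside short loops, of 10 kb loops with no longer loop beside them and of the odds ratio between ends and interior were chosen after the result had been seen. A dense island also occurred away from the chromosome ends. On chromosome 3 the leaf list rose from 8 ACRs at 42 to 43 Mb to 293 at 47 to 48 Mb, fell to 81 at 51 to 52 Mb, and returned to 293 at 54 to 55 Mb. The loop list, in its own coordinates, rose from 0 loops at 42 to 43 Mb of chromosome 3 to 38 at 49 to 50 Mb, fell to 16 at 54 to 55 Mb and reached 40 at 57 to 58 Mb. Whether these are the same island cannot be read from coordinates of different assemblies.

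Pairs of the shortest loops that lay end to end were about as frequent as pairs at nearby distances. Among 10 kb loops, 421 pairs started exactly 10 kb apart, so that one began in the bin where the other ended, against 376 pairs at 15 kb, 427 at 20 kb and 403 at 25 kb. This was a count with no test.

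The excess of 10 kb loops may be a short-range excess at the lowest distance listed, in proportion to the other short loops: the ratio of 10 kb to 15 kb loops was 7.92 at the ends and 8.25 in the interior, and the odds ratio of 10 kb against 15 to 25 kb loops, ends over interior, was 0.916 (exact 95% interval 0.751 to 1.11). By the test set beforehand, an excess spread evenly over the whole extent is excluded. Of the 10 kb loops, 88.2% lay at the ends (95% interval 87.2 to 89.2%), which hold 40% of that extent. Added to the level of 15 to 25 kb loops, such an excess would put 46.1% there, a figure worked out after the data were seen. Of the longer loops, 74.8% lay at the ends (95% interval 73.6 to 75.9%), a smaller share than of the 10 kb loops. Where loops could be called is not known, so an excess spread evenly over only that sequence was not tested. Removal of only the 15 and 20 kb loops beside a 10 kb loop would leave 25 kb loops. The 10 kb loops were 7.91 times as frequent as those (95% interval 7.20 to 8.70). No loop had another within 1 bin at both ends, whereas 2465 had one within 2 bins. This argues that adjacent calls were removed or merged, by a step that is not given. Merging of chains of neighbouring calls, which could reach longer spans, was not tested. Some 10 kb loops may be the remains of longer loops called beside them: 55.8% had an anchor in or next to that of a longer loop, just above the 52.7 to 55.6% of local shifts, as predicted beforehand for that explanation. Shifted loops could land where no loop could be called. Loops other than those of 10 kb also shared anchors more often than shifts, at 14.7% against 7.69%. The test therefore cannot tell such remains from anchors that cluster for other reasons. The longer loops listed beside them do not account for the whole excess. The 1730 with no longer loop beside them were 3.49 times as frequent as 25 kb loops (95% interval 3.16 to 3.87). Longer calls removed before listing would not be counted, so this cannot show how many 10 kb loops are such remains. No biological explanation was tested.

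Longer interior loops were weighed in the same way. They are not only the lack of 10 kb loops, since without those the interior median was still 4.30-fold that of the ends (95% interval 3.03 to 6.10). A distance expectation shared by regions whose contacts decay differently was not tested: the 28.2% of interior loops longer than 200 kb restate the pattern and give it no support. It cannot be told apart from longer loops in heterochromatin, because contact counts are not analysed here. Mappability of repeats is also untested.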
